A study of Mus musculus with 9 samples.

How the data were processed

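RNA from nuclei of mouse hippocampal pyramidal cells was measured in 9 libraries, 5 from cells classed as place cells and 4 from cells classed as silent cells. Per the labels, the cells were classed by in vivo imaging while mice navigated, their nuclei were tagged with light, nuclei were isolated, and libraries were made with the SMART-Seq mRNA LP kit, which amplifies polyadenylated RNA from small inputs. All libraries carry the genotype label WT. The submitters' processing notes name STAR, HTSeq and the GRCm39 genome build, with no tool version, role or order. The annotation, the strand setting of the counting and the normalization tool are not given in the sources used here. The reference annotation at hand is of the GRCm38 build, so no coordinates are printed, and genes are named by the symbols in the deposited table.

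The deposited table holds a normalized read signal, with libraries in rows and 31052 gene symbols in columns, and no library total is the same. How the values were scaled was worked out from the values. In all 8894 genes with a value above 0 in all 9 libraries, the values were whole multiples of 1 number per gene, shared by the 9 libraries, with each multiple within 0.05 of a whole number and the table printed to 3 decimals. That number was 3.18 at the median of the tested genes. In 8877 of these 8894 genes (99.8%) it matched, within 0.01 on the log2 scale, a trimmed mean of M-values (TMM) factor computed for each gene across libraries with Ezh2 as the reference gene. The values thus carry a factor per gene and none per library, and no label states this. Dividing by the gene's number gave whole reads for 20457 genes, among them all 15232 genes tested (100.0%). On simulated reads for 500 genes with reads in all 9 libraries, the procedure returned the true reads of all 500, up to a divisor common to a gene's reads. The later step that corrects for such a divisor was not simulated. Genes without reads in some library, 42.0% of those tested, were not simulated, and the match to the TMM factor given above does not cover them.

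The test planned before the data were examined was limma on log2(value + 1) of size-factor normalized values, or a count model if the table held raw counts. Because libraries were not scaled to a common depth, each library was first divided by a TMM factor computed across libraries (30% trim of M-values, 5% trim of A-values), and the values as deposited became an alternative. Genes with a value of at least 10 in at least 4 libraries were kept, a pseudocount of 1 was added, and limma 3.58.1 in R 4.3.3 was run with an intensity trend and no covariate, place minus silent, with Benjamini-Hochberg adjustment over 15232 genes and a threshold of 0.05. Fold changes are on this log2(value + 1) scale. The pseudocount can understate the change of low genes, while a library near 0 can make the fold larger than the ratio of mean levels. Bdnf, for example, had a log2 fold of 2.998 and a linear ratio of mean levels of 2.20, and Cldn11 6.10 and 7.80. A fold against a group with no reads depends on the pseudocount and is not printed. Levels are given in RPM, that is recovered reads per 1000000 of the library's TMM-scaled depth, as mean ± SD over libraries. All 9 library titles carry a mouse designation that runs on into a number, and the labels do not state whether each library is a separate animal. The p-values then measure only the spread between these libraries.

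Before the data were examined, 35 gene lists were fixed: markers of hippocampal and other cell types, activity-response genes, receptors, channels, synaptic machinery, signalling, energy supply, translation, stress, chromatin, noncoding RNA, sex-linked genes, cytoskeleton and protein breakdown. The 33 lists with at least 5 tested members were compared with all other genes by limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 33 lists. Camera with an estimated correlation, camera on ranks and fry, which asks whether a list's genes move on balance one way, were alternatives. The genes named in the text follow a rule fixed at the same time. It takes the 10 genes with the smallest p in each direction, leaving out predicted-model symbols, up to 4 members with the smallest p of each list past the threshold, and 13 genes named in advance. Xist and Tsix, the X-linked members of the sex-linked list, fall outside the rule and were named after their values were seen. Other genes whose levels are named outside it are said to be so chosen.

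Library-level measures (genes detected, recovered depth, shares of reads and mean log2 value of marker lists of other cell types) were compared by exact permutation tests, two-sided, over all 126 splits of 5 and 4 libraries. The smallest p these allow is 0.00794, so that a measure alone in reaching it would have an adjusted p of 0.111 over the 14 measures.

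The gene test was tested on simulated data for the place against silent comparison, with 200 changed genes. At a dispersion of 0.1, 28 of 67 genes changed 2-fold, all 67 changed 4-fold and all 66 changed 16-fold were recovered among 15208 genes tested, with 8 false calls. At the dispersion of these libraries the figures were 2 of 67, 10 of 67 and 28 of 66 among 14954 genes tested, with 3 false calls. In 20 simulated tables with no change, 1 had any list past the threshold. With the oxidative phosphorylation list shifted 1.5-fold, all 20 tables had it past the threshold. These simulations draw genes independently and do not hold the correlation between genes.

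Alternatives changed the pseudocount (0.5 or 10), the filter, the scaling, library weights, a covariate for the number of genes detected, the test (voom on the recovered reads, an exact rank-sum test) and left out each library in turn. Added after seeing the data were a covariate for the mean log2 value of 4 Y-linked genes, a fit without the 3 libraries furthest out on the first 3 principal components, and the list test on voom values. Transcript lengths came from the longest transcript per symbol in GENCODE M21, with older symbols matched through the RefSeq gene table of assembly GRCm38.p6. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.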

Results

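Nuclear RNA was profiled in 9 libraries from mouse hippocampal pyramidal cells, the principal excitatory neurons of the hippocampus. Cells had been classed during spatial navigation as place cells, which fire at particular locations, or as silent cells, and their nuclei were phototagged and collected. The place group held 5 libraries and the silent group 4. Recovered depth, in units of 1000000 reads, ran from 13.999 in silent replicate 1 to 22.3 in silent replicate 4, and averaged 18.4 ± 2.47 (SD, n = 5) in place and 18.1 ± 3.71 (SD, n = 4) in silent libraries. Pyramidal neuron transcripts were abundant in both groups. Camk2a, the alpha subunit of a calcium-dependent kinase of excitatory synapses, stood at 1025 ± 141 RPM (SD, n = 5) in place and 1081 ± 252 (SD, n = 4) in silent libraries. Gria1, an AMPA receptor subunit, stood at 1603 ± 98.8 and 1462 ± 206. Wfs1, a marker of CA1 pyramidal cells, stood at 134 ± 67.6 and 148 ± 31.7.

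The libraries were unlike one another within each group. Correlations of log2 values between pairs of libraries lay between 0.549 and 0.767, and no pair held identical values. The first principal component (22.9% of the variance) set silent replicate 1 apart, the second (16.5%) silent replicate 4, the third (15.7%) place replicate 3 and the fourth (14.3%) place replicate 1. Genes detected numbered 18603 ± 1936 (SD, n = 5) in place and 16091 ± 1606 (SD, n = 4) in silent libraries, from 14176 in silent replicate 1 to 20990 in place replicate 2 (exact permutation test, two-sided, p = 0.0952, adjusted p = 0.444 over 14 measures). Of the 15232 genes tested, 42.0% lacked reads in at least 1 library. No library-level measure passed the threshold, which a single one could not do at this size (smallest adjusted p 0.111). Mean log2 value of oligodendrocyte markers was 9.90 ± 2.02 in place and 6.56 ± 1.248 in silent libraries (exact permutation p = 0.0317, adjusted p = 0.222), and that of CA3 pyramidal markers 6.87 ± 0.67 and 5.25 ± 0.99 (exact permutation p = 0.0238, adjusted p = 0.222). Mitochondrially encoded genes took 0.0741 ± 0.0675% and 0.0592 ± 0.0131% of reads, and place replicate 3 was highest at 0.191%.

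Sex-linked transcripts were spread unevenly over the groups. Eif2s3y, a Y-linked translation factor gene, was present in all 4 silent libraries, from 346 to 807 RPM, and in place replicate 1 at 695, and had no reads in the other 4 place libraries. Ddx3y, Uty and Kdm5d, also Y-linked, were at 28.0 RPM or more in the same 5 libraries and at most 0.264 in the rest. Xist, the noncoding RNA that silences 1 X chromosome in females, was at 1022 ± 290 RPM (SD, n = 4) in the 4 libraries without Y-linked transcripts and at most 2.89 in 4 of the 5 with them. Silent replicate 1 held both, with Xist at 316 and Eif2s3y at 545 RPM. The labels give no sex. Tsix overlaps Xist on the opposite strand, and the strand setting is not given, so its reads are uncertain. Tsix did not follow Xist in every library. It stood at 22.7 RPM in place replicate 1 and 17.5 in silent replicate 4, where Xist was at 1.72 and 0.0437. In the other silent libraries Tsix was at most 2.35, and in place replicates 2 to 5 it was at 7.01 to 27.3. Y-linked genes can share reads with X-linked relatives, here chosen after their values were seen. In place replicates 2 to 5, Ddx3x stood at 203 to 342 RPM, Kdm5c at 79.1 to 124, Kdm6a at 20.9 to 57.3 and Eif2s3x at 9.49 to 22.1. With each Y-linked gene at most 0.264 there, these values argue against X-linked reads making up the Y-linked counts.

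**Figure D1:**
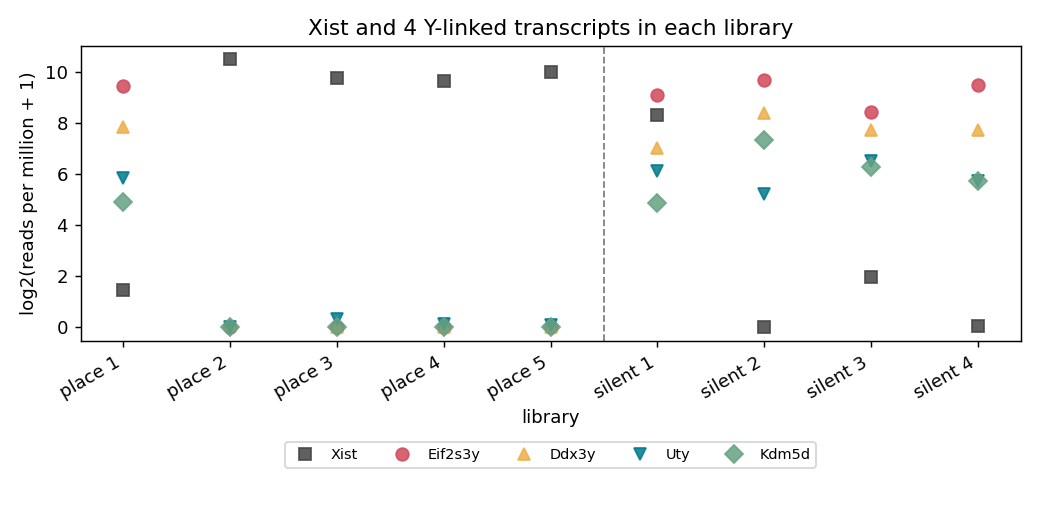
Levels of Xist and 4 Y-linked transcripts, as log2(RPM + 1) on the vertical axis, in each of the 9 libraries on the horizontal axis, with place libraries left of the dashed line. Eif2s3y has no reads in place replicates 2 to 5, and silent replicate 1 has both Xist (316 RPM) and Eif2s3y (545).

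The comparison of place with silent cells asks which transcripts differ between functionally identified cells, all of them labelled as hippocampal pyramidal cells. The genes with the smallest p in place libraries were seen in all 5 of them, and in silent ones had no reads (7 of 10) or at most 0.977 RPM. Spock1, which encodes a secreted proteoglycan, was at 27.6 ± 16.8 RPM (SD, n = 5) in place libraries and had no reads in any of the 4 silent ones. Adi1 (18.5 ± 28.4, a methionine salvage enzyme), Chmp1b (22.7 ± 20.8, an ESCRT membrane-scission component), Zfp977 (10.8 ± 6.69), Gpr83 (10.9 ± 7.35, a G protein-coupled receptor), Pcdha8 (5.46 ± 3.88) and Utp14b (5.86 ± 9.80) showed the same layout. Pms1 (a mismatch repair gene) stood at 11.3 ± 7.48 in place and 0.0109 ± 0.0218 in silent libraries, Sned1 at 18.0 ± 17.8 and 0.0388 ± 0.0268, and the collagen gene Col16a1 at 26.2 ± 18.2 and 0.255 ± 0.482. Pcdha8 shares exons with the other alpha protocadherins and Utp14b lies within another gene, so their counts are uncertain.

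Among the genes with lower values in place libraries, Kcnj12, an inward rectifier potassium channel gene, had no reads in 5 of 5 place libraries and stood at 8.73 ± 6.26 RPM (SD, n = 4) in silent ones. Hexim2, an inhibitor of transcription elongation, averaged 0.0422 ± 0.0943 and 15.1 ± 5.20. Other genes were expressed in every library and had non-overlapping groups. Full separation of 5 and 4 libraries has an exact rank-sum p of 0.0159 before adjustment, so many of 15232 genes would show it by chance. Cdh11, a cadherin adhesion molecule, stood at 151 ± 26.3 in place and 282 ± 21.97 in silent libraries (log2 fold -0.92 ± 0.22 SE, limma adjusted p = 0.671). Ahsa1, an activator of the chaperone HSP90, stood at 30.6 ± 7.66 and 91.4 ± 40.8 (-1.52 ± 0.37, limma adjusted p = 0.671), Herc4, a ubiquitin ligase gene, at 53.5 ± 26.9 and 157 ± 27.9, and Mospd2 at 26.2 ± 16.2 and 117 ± 62.6. Zfp763 stood at 16.04 ± 22.7 and 95.02 ± 53.3, and its groups overlapped. Eif2s3y, Ddx3y and Kdm5d made up the 10.

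None of these differences passed the threshold. With limma, 0 of 15232 genes had an adjusted p under 0.05 in either direction, and the smallest adjusted p was 0.433. At an unadjusted p under 0.05 there were 763 genes, 589 with higher and 174 with lower values in place. The nominal number by chance is 761.6, and the median over 100 splits of the libraries was 578.5. The tested genes as a whole leaned the same way (median log2 fold 0.22), and fewer genes were detected in silent libraries. Voom on the recovered reads called 4 genes, Spock1, Gm44750 and 2700029L08Rik with higher and Hexim2 with lower values in place (smallest adjusted p 0.0393). The exact rank-sum test called 0, which says little, since 4836 genes would have to reach its smallest p of 0.0159 for any to pass. Gm44750 and 2700029L08Rik were chosen after their values were seen. Leaving out place replicate 1, the place library with Y-linked transcripts, left 1 gene past the threshold, Eif2s3y (limma adjusted p = 0.0239).

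**Figure D2:**
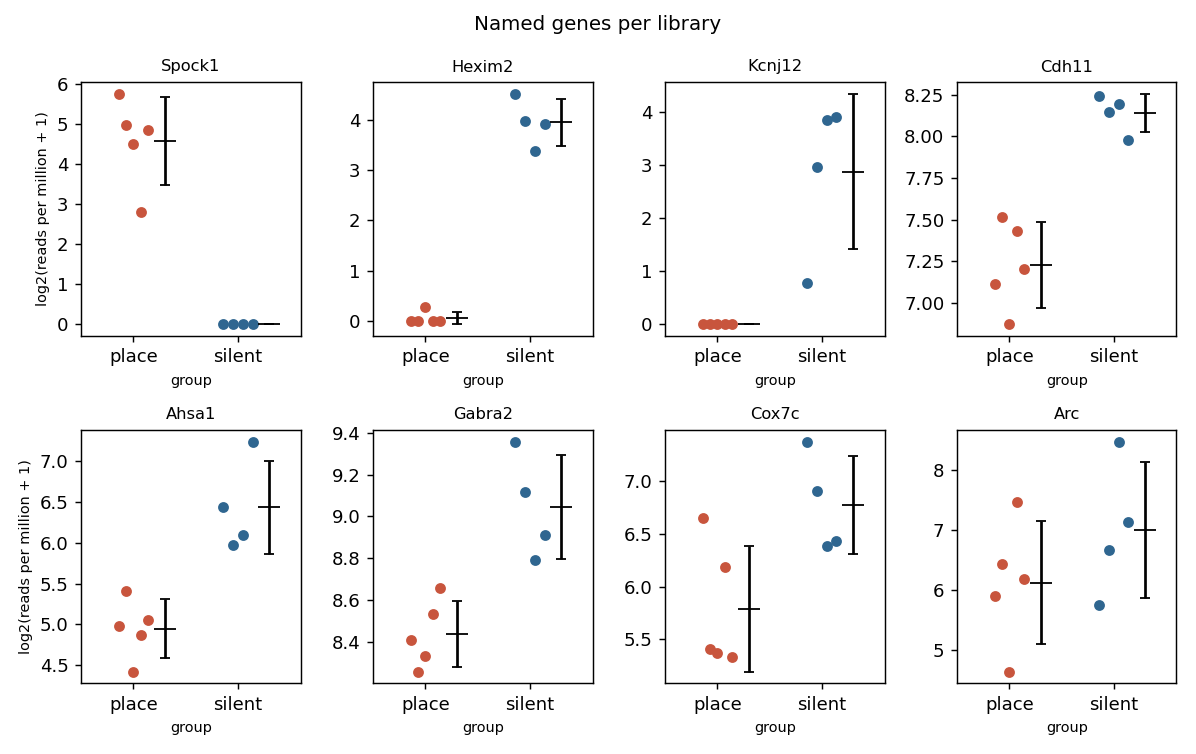
Levels of 8 named genes as log2(RPM + 1), each point a library, with place in red and silent in blue and a bar for the mean ± SD, on a separate vertical axis per gene. Spock1 has no reads in silent libraries and Kcnj12 none in place libraries, while the groups of Cdh11, Ahsa1 and Gabra2 do not overlap and those of Arc do.

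Of the gene lists, 5 of 33 passed the camera threshold, 4 with lower and 1 with higher values in place. Over 100 splits of the libraries, the real one included, the median was 1.5 lists and 11 splits gave at least 5. Adjusted p values of single lists are thus smaller than arbitrary groupings of these libraries warrant. Nuclear-encoded oxidative phosphorylation genes, which build the respiratory chain, were lower in place libraries as a group (66 members, median log2 fold -0.23, adjusted p = 0.00044, and adjusted p = 0.351 with an estimated correlation). The fold was negative in 49 members and positive in 17, against a median of 0.22 over all tested genes. No member passed the threshold over all genes or adjusted over the list alone. Cox7c, a cytochrome c oxidase subunit, stood at 58.6 ± 26.8 RPM (SD, n = 5) in place and 113 ± 38.4 (SD, n = 4) in silent libraries, Cox7b at 60.2 ± 32.2 and 125.8 ± 57.9, and Ndufa6 at 39.1 ± 11.6 and 76.5 ± 32.3. Ndufs1, a complex I subunit, went the other way, at 214 ± 54.8 and 129 ± 47.2. Genes detected were fewer in the silent group, and with their number in the fit the adjusted p was 0.317. Without silent replicate 4 it was 0.0541.

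Cytosolic ribosomal protein genes were also lower in place as a list (84 members, median log2 fold -0.14, adjusted p = 0.0105, and adjusted p = 0.11 with an estimated correlation). Negative folds were found in 47 members and positive ones in 37, and no member passed over all genes or adjusted over the list alone. Rpl35 stood at 10.6 ± 3.01 RPM in place and 25.5 ± 3.86 in silent libraries, Rps25 at 26.4 ± 5.09 and 72.9 ± 61.4, Rps24 at 65.9 ± 30.4 and 107 ± 29.8, and Rpl13 at 72.2 ± 18.8 and 45.9 ± 8.01. Genes of both lists have processed pseudogenes that can share reads, so single members are uncertain. Without silent replicate 1 or silent replicate 4 the adjusted p was 0.0927 or 0.0920. Quantile normalization moved the median fold of all tested genes from 0.22 to 0.01 and ended both calls (adjusted p = 0.0694 for each).

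The GABA receptor and inhibitory postsynapse list was lower in place (16 members, median log2 fold -0.19, adjusted p = 0.0351, and adjusted p = 0.351 with an estimated correlation), with 11 negative and 5 positive members. Gabra2, a GABA-A receptor alpha subunit, stood at 347 ± 38.9 RPM in place and 533 ± 93.9 in silent libraries (log2 fold -0.61 ± 0.18 SE, limma adjusted p = 0.824), with no overlap between the groups. Gabra3 stood at 17.8 ± 9.88 and 39.0 ± 19.7, and Gabra4 at 181.7 ± 36.6 and 244 ± 56.3. No member passed over all genes or adjusted over the list alone. The call was lost in 14 of 24 alternatives, among them leaving out silent replicate 1 (adjusted p = 0.120), silent replicate 3 (0.212), silent replicate 4 (0.0723), place replicate 2 (0.106), place replicate 3 (0.0599) or place replicate 5 (0.0578).

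Oligodendrocyte markers, genes of the myelin-forming glia, were higher in place libraries as a list (11 members, median log2 fold 3.39, adjusted p = 0.00527, and adjusted p = 0.657 with an estimated correlation), with 10 positive members and 1 negative. Opalin stood at 25.3 ± 31.9 RPM in place and 0.0178 ± 0.0356 in silent libraries, Cldn11 at 114 ± 91.2 and 14.6 ± 20.6, Ugt8a at 16.3 ± 13.0 and 1.06 ± 2.04, and Cnp at 57.8 ± 48.4 and 9.32 ± 11.1. Adjusted over the list alone 3 members passed (Opalin, Cldn11 and Ugt8a), and over all genes 0. The list's level per library was highest in place replicates 1, 2 and 3. Without place replicate 3 or silent replicate 4 its adjusted p was 0.0599 or 0.0723. The sex-linked list was lower in place (6 members, median log2 fold -8.47, adjusted p = 0.00631, and adjusted p = 0.377 with an estimated correlation), with the 4 Y-linked members negative and Xist and Tsix positive. Adjusted over the list alone 6 members passed, and over all genes 0. Tsix was among the 6, although it did not follow Xist in every library. Without silent replicate 1 or silent replicate 4 the adjusted p was 0.0927 or 0.0723, and it was 0.543 with camera on ranks and 0.569 with the number of genes detected in the fit.

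**Figure D3:**
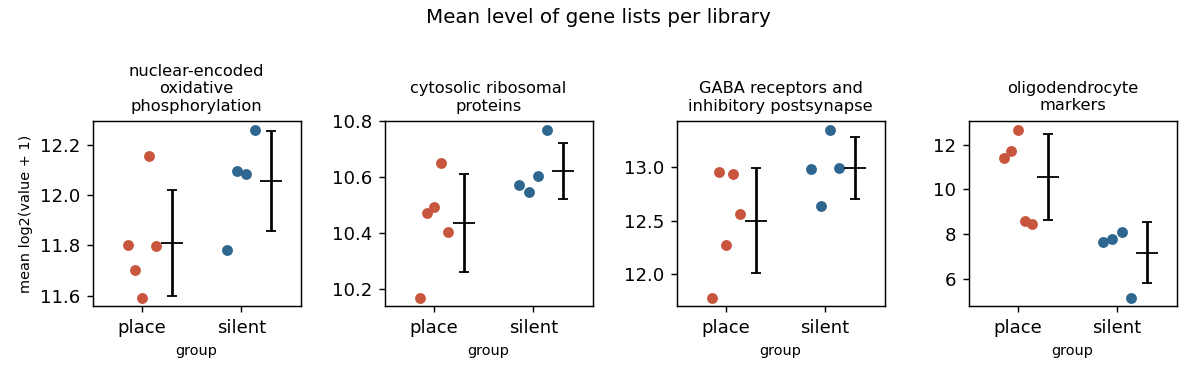
Mean log2(value + 1) of the tested members of 4 gene lists, each point a library, with place in red and silent in blue and a bar for the mean ± SD, on a separate vertical axis per list. The list means were 11.81 ± 0.21 and 12.05 ± 0.20 for oxidative phosphorylation and 10.56 ± 1.93 and 7.15 ± 1.36 for oligodendrocyte markers, place first.

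Immediate early genes, which neurons transcribe within minutes of activity, did not pass as a list (18 members, adjusted p = 0.533), although with the number of genes detected in the fit the list was lower in place (adjusted p = 0.00131), as it was with the Y-linked level in the fit (0.0353) and without silent replicate 1 (0.0499). With an estimated correlation, without these changes, it had an adjusted p = 0.959. Arc stood at 83.0 ± 56.9 RPM (SD, n = 5) in place and 162 ± 134 (SD, n = 4) in silent libraries, Fos at 26.4 ± 42.0 and 21.3 ± 19.8, Npas4 at 25.6 ± 30.7 and 31.1 ± 20.2, Egr1 at 139 ± 125 and 193 ± 115, and Nr4a1 at 96.9 ± 80.3 and 127 ± 21.4. Homer1 stood at 399 ± 106 and 475 ± 59.6. Bdnf, a secreted neurotrophin on the late activity-response list, stood at 78.0 ± 33.4 and 35.4 ± 45.3 (log2 fold 2.998 ± 1.47 SE, limma adjusted p = 0.861), with overlapping groups and a log2 fold of 1.07 without silent replicate 1, where it was at 0.142 RPM. Calb1, a calcium-binding protein of superficial CA1 and dentate granule cells, stood at 166 ± 82.8 and 155 ± 118. Kcnq3, a potassium channel gene, stood at 284 ± 34.5 and 226 ± 67.5.

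Cell type lists other than oligodendrocytes gave adjusted p values of 0.147 for CA1 pyramidal markers (0.0335 and lower in place without place replicate 1, and adjusted p = 0.870 over all libraries with an estimated correlation), 0.225 for CA3, 0.687 for CA2 and for general excitatory neurons, 0.843 for dentate granule cells, for astrocytes and for CA1 deep, superficial and long-axis markers, and 0.941 for interneurons, microglia and oligodendrocyte precursors. Of the tested members, 6 of 6 CA3 markers had positive folds, while 9 of 11 CA1 markers had negative and 2 positive ones. As single libraries were left out, the adjusted p of CA1 pyramidal markers ran from 0.0335 to 0.655. Their mean log2 value was lowest in place replicate 3 (11.42, next lowest 12.81 in place replicate 5). Dcn on the CA1 axis list and Npy on the interneuron list, each with reads in 5 place and 0 silent libraries and each chosen after its values were seen, passed adjusted over the list alone and not over all genes. Vascular and choroid plexus lists had 3 and 2 tested members and were not tested as lists. Of the choroid plexus members Enpp2, chosen after its values were seen, passed adjusted over the list alone, at 227 ± 156 in place and 60.3 ± 25.5 in silent libraries. That adjustment covers only 2 genes, and the other tested member had a negative fold. For Dcn, Npy and Enpp2 alike, adjustment over a list alone does not correct for the number of lists looked at, so such passes may arise by chance. Over all 6 measured members the mean log2 value was 4.55 ± 0.36 in place and 4.39 ± 1.10 in silent libraries (exact permutation p = 0.786, adjusted p = 0.913).

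The remaining lists did not pass either. The ubiquitin-proteasome list had an adjusted p of 0.0881, and was past the threshold and lower in place without silent replicate 1 (0.0499), place replicate 1 (0.0335) or place replicate 4 (0.0424), with no filter on low values (0.0164) and with voom (0.0434). Its adjusted p = 0.870 with an estimated correlation and none of these changes. The adjusted p was 0.843 for late activity-response genes, potassium channels, kinase, phosphatase and calcium signalling, the p53 and DNA damage response, and nuclear-retained noncoding RNAs. It was 0.856 for metabotropic glutamate receptors, 0.859 for AMPA receptor auxiliary subunits and scaffolds, and 0.866 for synaptic adhesion molecules and mitochondrially encoded genes. It was 0.941 for ionotropic glutamate receptors, sodium, calcium and HCN channels, presynaptic release machinery, glycolysis, stress and heat-shock genes, chromatin regulators, and the cytoskeleton. The mitochondrially encoded list was past the threshold and higher in place with the number of genes detected in the fit (0.0401). Its adjusted p = 0.959 with an estimated correlation and without that number, and its direction was the opposite with array weights, without place replicate 3 and without the 3 libraries set apart by the first 3 components. Camera with an estimated correlation and fry each called 0 of 33 lists, and camera on ranks called 4. The mixed form of fry, which asks whether a list's genes change in either direction, put only the cytoskeleton list past the threshold (adjusted p = 0.0070). That list had 20 positive and 8 negative members, and 0 passed adjusted over the list alone.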

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

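In this part the tests on zeros, on the Y-linked level, on the number of genes detected, on correlation within lists and on Xist were chosen after the results were seen, while those on other splits of the libraries and on transcript length were fixed before. Of 136 groups of libraries checked for a value far from its neighbours, 16 had one, where chance gives about 1 in 20 (6.8). Some are genes with reads in only 1 library of the group, which then always counts as far out. The chance figure does not hold for these.

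Y-linked transcripts gave 5 of the 16, as place replicate 1 stood alone in the place group with Eif2s3y at 695 RPM (next highest 0), Ddx3y at 230 (0.0577), Uty at 56.0 (0.264), Kdm5d at 28.9 (0) and a mean log2 value of the sex-linked list of 11.01 (4.99). Mice of both sexes, split unevenly between the groups, may account for this: in 8 of 9 libraries exactly 1 of Xist and the Y-linked transcripts was above 10 RPM. In silent replicate 1, where both were, Xist was at 31.0% of the mean of the 4 libraries without Y-linked transcripts, against at most 2.89 RPM in the other libraries with them, so RNA of a second animal stays open there, and no value separates it from other sources. Functional class alone does not give this layout. Place replicate 1 held Y-linked transcripts, while each was at most 0.264 RPM in the other place libraries. Y-linked transcripts were present in all 4 silent and in 1 of 5 place libraries, so sex and functional class are nearly confounded. For other genes a difference tied to class stays open, and sex cannot be told apart from it.

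Oxidative phosphorylation and ribosomal protein genes were lower in place libraries as lists, and neither passed with an estimated correlation (adjusted p = 0.351 and 0.110). Short transcripts, which both lists hold (median length 1141 and 1054 bases against 3161), are not excluded. A share of 0.0019 and 0.0222 of 10000 random lists matched on length and level had a mean statistic as low. Those lists draw genes independently and lack the correlation between members, and only 57 of 66 oxidative phosphorylation members had a length. Across genes the statistic hardly followed log2 length (correlation 0.0037). Zeros in libraries with few genes detected stay open for both lists. Among genes above 0 in all 9 libraries, camera at the preset correlation gave an adjusted p of 0.0129 for oxidative phosphorylation and 0.273 for ribosomal proteins. The first list kept 65 of its 66 members, so mainly the genes it was compared with changed, and this cannot decide the question. With the number of genes detected in the fit, the oxidative phosphorylation difference from all genes went from -0.84 ± 0.30 (SE) to -0.28 ± 0.18. That of ribosomal proteins went from -0.78 ± 0.32 to -0.18 ± 0.19, so those calls ended because the difference shrank. Without that number in the fit, the lists' own mean log2 folds were only -0.24 and -0.19. Most of each first difference thus came from higher values of the other genes in place libraries, not from lower values of the list genes. Sex cannot be told apart from the groups here, since with the Y-linked level in the fit (adjusted p of 0.687 and 0.368) the contrast rests on place replicate 1, and a difference tied to functional class stays open too.

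The chance of such a result was judged on 100 splits of the libraries into 5 and 4, the real one included. As many lists as the real 5 were past the threshold in 11 splits (highest other split 7, median 1.5), so chance cannot be excluded as the origin of the number of lists. As many genes at an unadjusted p under 0.05 as the real 763 came from 12 splits (highest other 1154, median 578.5), so chance cannot be excluded there either. For genes past the threshold the real count was 0, which all 100 splits reach by construction (highest other 3), so this says nothing about chance.

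Oligodendrocyte markers were higher in place libraries as a list, though not past the threshold with an estimated correlation (adjusted p = 0.657), and silent replicate 4, at a mean log2 value of 4.70, was far below the other silent libraries (next 7.01). Fewer genes detected in silent libraries are not excluded. With that number in the fit, the list's difference from all genes did not shrink, going from 2.81 ± 1.26 (SE) to 3.84 ± 1.59. Camera gave an adjusted p of 0.000476 in that fit, but at the preset correlation of 0.01, below that found between members. RNA or nuclei of oligodendrocytes in some libraries is a candidate explanation: within groups the markers varied together more than in 99.7% of 10000 random lists matched on level (mean correlation 0.298), and Mbp, an abundant member, stood at 134 ± 94.5 RPM in place and 59.8 ± 25.3 in silent libraries (SD). Mbp was chosen after its values were seen, none of the 12 markers is on another list, and phototagging of pyramidal cells is the step that would leave such nuclei out. A difference tied to functional class stays open and was not tested apart from it.

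The other values far from their group were these. Place replicate 3 had 0.191% of reads in mitochondrially encoded genes (next 0.0682%), Utp14b at 23.4 RPM (next 1.99) and Hexim2 at 0.211 (next 0). Place replicate 1 had a mean log2 value of CA2 markers of 1.87 (next lowest 4.84). Silent replicate 2 had a mean log2 value of all 13 astrocyte markers of 10.05 (next 5.80), Col16a1 at 0.977 RPM (next 0.0437) and Ugt8a at 4.11 (next 0.0711). Silent replicate 4 had Pms1 at 0.0437 (next 0), silent replicate 1 Opalin at 0.0711 (next 0) and silent replicate 3 Wfs1 at 101 (next lowest 161).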

How the results depend on the processing

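The covariate for Y-linked genes, the fit without 3 libraries and the list test on voom values were added after seeing the data. A count of 0 genes past the threshold held under 18 of 21 alternatives, the rank-sum test left aside because its smallest p all but rules out a call. Voom on the recovered reads gave 4 genes, and the Y-linked covariate gave 220, all lower in place, in a fit whose contrast rests on place replicate 1. Leaving out each library gave 0 to 1. The count of 5 lists became 1 among genes above 0 in all 9 libraries, where 23 lists could be tested, 2 with quantile normalization, 3 with the number of genes detected as covariate, 0 with an estimated correlation, 0 with fry, 2 with the Y-linked covariate and 0 without silent replicates 1 and 4 and place replicate 3. Leaving out each library gave 0 to 7 lists, with 0 without silent replicate 4 and 3 without place replicate 3. The cause was not tested except where stated. Over alternatives the adjusted p ran from 3.4e-06 to 0.687 for oxidative phosphorylation and from 0.00336 to 0.606 for ribosomal proteins. The 28 lists not past the threshold were given a direction only where an alternative put them past the threshold, and camera or fry gave the opposite one in 109 of 664 cases.

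Of the 50 genes that the naming rule takes, 5 changed sign, none past the threshold, and 5 others gained a call in 1 alternative each: Spock1 and Hexim2 with voom (adjusted p = 0.0393 for each), Cox7b (0.0371) and Egr1 (0.0378) with the Y-linked covariate, and Eif2s3y without place replicate 1 (0.0239). Fos went from a log2 fold of -0.049 to 0.00046 with a pseudocount of 0.5, 0.17 with array weights and 2.47 with the Y-linked covariate, and from -2.90 to 2.08 as libraries were left out. Wfs1 became 0.0894 with the Y-linked covariate and 0.30 without the 3 libraries (-0.58 to 0.11 as libraries were left out), Npas4 0.36 with array weights, and Calb1 -0.0758 with the number of genes detected (-0.33 to 1.01). Camk2a ran from -0.20 to 0.0767. That no library-level measure passed in any alternative says nothing of stability, since a single one could not pass at this size. With libraries left out, the place minus silent difference ran from -1.13 to 1.62 for reads in units of 1000000, -0.216 to 0.457 percentage points for the top 50 genes, -0.0142 to 0.0266 for mitochondrial genes, and in mean log2 value from -0.31 to 0.78 for CA2, -0.42 to 1.04 for dentate granule, -0.47 to 0.60 for interneuron, -2.03 to 0.26 for oligodendrocyte precursor, -0.0335 to 2.21 for microglia and -0.11 to 0.70 for choroid plexus markers. The count model edgeR, planned as the main test had the table held raw counts, was not run, nor was DESeq2. Voom on the recovered reads was run in their place, so no count model was fitted although whole reads were recovered for all tested genes. No paired analysis was possible because replicate numbers were given in accession order and no label pairs the libraries. The median SE of the log2 fold was 1.32 over all tested genes and 0.56 in those seen in all 9 libraries. Dropout may widen it in low genes, which was not tested.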

Other observations

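Immediate early genes varied more between libraries than between groups. The mean log2 value of the list was 12.51 in place replicate 4, 12.28 in silent replicate 3 and 11.94 in place replicate 2, and 7.18 in silent replicate 1 and 8.27 in place replicate 1. Arc ran from 23.7 RPM in place replicate 3 to 355 in silent replicate 3, and Egr1 from 6.74 in place replicate 1 to 335 in silent replicate 3. Glial markers also differed between libraries of 1 group. Over the 11 tested members of each list, astrocyte markers had a mean log2 value of 12.89 in place replicate 3 and 11.24 in silent replicate 2, against 5.61 in silent replicate 4, and microglia markers one of 10.17 in place replicate 2, 9.98 in place replicate 5 and 9.37 in silent replicate 4, against 2.997 in place replicate 1.

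The tests of these lists were chosen after their levels were seen, and that of all-or-none genes before. A shared activity state of the nuclei in a library is a hypothesis for the immediate early genes, whose mean correlation within groups (0.416) was above that of 100% of 10000 random lists matched on level. RNA or nuclei of other cells in some libraries may account for the astrocyte and microglia markers, with mean correlations of 0.319 and 0.378, above 99.8% and 99.95% of matched lists, although phototagging of pyramidal cells would leave such nuclei out. These lists were taken up because their mean values differed widely between libraries, which members that vary together bring about. The correlations thus restate that spread and cannot decide for any of these explanations. Handling of single libraries could give the same values and was not tested.

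A hypothesis that all-or-none genes mark the groups was tested by counting tested genes with reads in every library of one group and in none of the other. There were 36, of which 34 were seen in place libraries and 2 in silent ones (Kcnj12 is one). Of all splits of the libraries into 5 and 4, 7 gave as many (highest other split 48, median 9), so chance cannot be excluded for this number.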
